A study of Mus musculus with 6 samples.

How the data were processed

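Ribosome-bound mRNA of mouse cardiomyocytes was sampled in 6 libraries, 3 given vehicle (control) and 3 given tamoxifen (treated). Per the labels' protocols, RNA was obtained by translating ribosome affinity purification, in which ribosomes carrying a tag are pulled down with the mRNAs they hold, and polyadenylated RNA was made into Lexogen QuantSeq libraries, which place reads near the 3′ end of each mRNA. Levels therefore reflect both the amount of an mRNA and its loading on ribosomes. Per the submitters' processing notes, RSEM 1.2.3, DESeq2 (no version given) and the mm10 genome build were used; the aligner, the annotation and any filter are not given in the sources used here. The deposited table holds whole-number counts per gene for the 6 libraries. RSEM estimates counts and shares reads between similar genes, so the authors may have rounded its estimates before deposit, and genes with near-identical copies, such as ribosomal protein genes and their pseudogenes, are uncertain. No molecular identifiers are named, so reads are not independent molecules and the count of reads overstates the precision of a low gene.

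Table columns were matched to samples by name, and groups and replicate numbers came from the sample titles. The table holds 38887 gene identifiers, 37570 of which were matched to a symbol, with coordinates from the GENCODE annotation of the same build. Chi-square comparisons of all pairs of libraries found none that agree within sampling noise, so all 6 were counted. Spearman correlations between libraries, taken across genes, were 0.692 to 0.737 within groups and 0.674 to 0.769 between groups. Library totals were 23057044 to 27545424 counts, with TMM factors of 0.929 to 1.03.

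Tests were run in R 4.3.3. The main test was edgeR 4.0.16 (TMM factors, filterByExpr with a minimum count of 10, quasi-likelihood F-test, group as the only term, 2-sided), with Benjamini-Hochberg adjustment over the 7901 genes kept and a threshold of 0.05. CPM values use TMM-adjusted library sizes, and the SE is the absolute log2 fold change divided by the square root of the F statistic. Gene lists, 50 in all, were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation of 0.01, and at least 5 tested members; camera was repeated with an estimated correlation, and fry was run as a second set test. The summed CPM of each list was compared with limma on the log2 scale to give 95% intervals, a step chosen after seeing the data. The sum gives most weight to the most abundant members, while camera weights members equally.

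The test, the lists, the alternatives and the naming rule were fixed before the data were examined. By that rule the text names Lmna first, then the 10 genes with the largest rise and the 10 with the largest fall among called genes with at least 10 CPM in the higher group and no overlap between groups, then up to 4 called members of each list. Where no member of a list was called, the 2 members with the highest mean CPM were available as values. No gene qualified under the second part, and some values under the rule are not reported here. Other genes named are said to be chosen after their values were seen, or belong to a list under the rule, as Nppa does as the most abundant atrial marker.

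The edgeR, DESeq2 1.42.0, limma-voom and camera steps were tested on simulated counts drawn from the real means and library sizes. The spread of each simulated gene followed the dispersion trend over abundance estimated from the data, with no gene-specific part. With 200 changed genes drawn from all tested genes, edgeR made 45 calls of which 3 were false, DESeq2 163 of which 105 were false, and limma-voom 32 of which 3 were false. With 200 changed genes drawn from those of at least 100 CPM, false calls were 11 of 140, 147 of 295 and 5 of 115. Camera called 5 of 6 lists shifted by 1 on the log2 scale, 6 of 6 shifted by 2, and 0 others; the simulated genes were independent of each other. Alternatives were DESeq2, limma-voom, RLE and upper-quartile factors, no filter on low counts, a minimum count of 50, robust dispersion, a block for replicate number, and leaving out each library in turn. A further one without mitochondrially encoded genes was not run, since the table holds 0 of them. Added after seeing the data were tests of genes with at least 100 CPM (edgeR and DESeq2), counts of 4 pseudogenes added to their parents, fry in either direction, and limma on summed CPM. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3.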

Results

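Messenger RNA bound to ribosomes was collected from mouse cardiomyocytes, the contracting cells of the heart, and 6 libraries were compared. The treated group received tamoxifen (3 libraries) and the control group received vehicle (3 libraries). The series title names LMNA cardiomyopathy, a heart muscle disease linked to the gene for the nuclear lamins A and C, and stress responses in its development. The labels do not say how tamoxifen acts in these cells, so the comparison is described here only as tamoxifen against vehicle. Total counts were 25648681, 25070590 and 25646026 in control replicates 1 to 3 and 25385143, 27545424 and 23057044 in treated replicates 1 to 3. Between 7974 and 9516 genes had at least 1 read per library, 12566 genes had a read in any library, and 5162 had one in all 6. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these libraries, part of which may be technical.

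Contractile genes dominated all 6 libraries. The 24 genes of the sarcomere list, which code for the contractile apparatus, took 23.5, 29.7 and 28.8% of the counts in control replicates 1 to 3 and 23.8, 22.2 and 23.7% in treated replicates 1 to 3. Myl3, the ventricular essential myosin light chain, alone took between 7.89 and 16.1%. Nuclear-encoded respiratory chain genes summed to 65831 ± 2021 and 69967 ± 7186 CPM with vehicle and tamoxifen, and ribosomal protein genes to 20037 ± 2263 and 20905 ± 2578 CPM. CPM are counts scaled to the TMM-adjusted library size, given as mean ± SD (n = 3 per group). Genes of low abundance were often lost from single libraries. For this count CPM were scaled to the library total without TMM factors. Of genes with a mean of 5 to 10 CPM in the other 5 libraries, 40.2% of gene-library pairs held 3 reads or fewer, against 0.304% at 100 to 200 CPM.

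**Figure D1:**
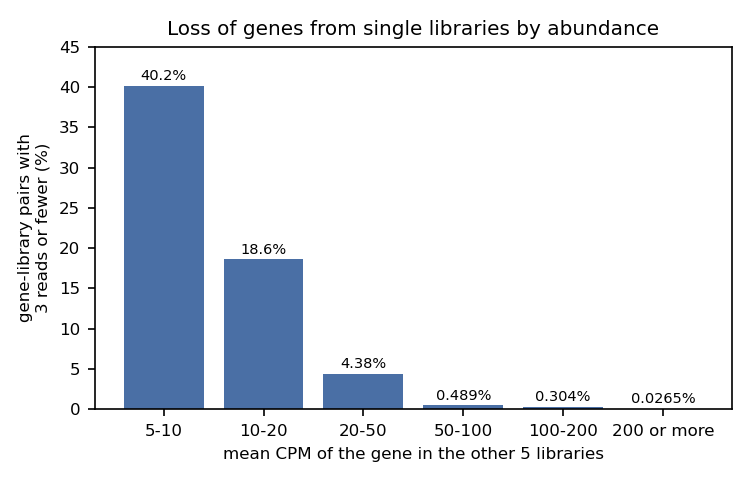
Share of gene-library pairs with 3 reads or fewer (y axis, percent) by the mean CPM of the gene in the other 5 libraries (x axis), over all 6 libraries. CPM here are scaled to the library total without TMM factors. The bars fall from 40.2% at 5 to 10 CPM to 4.38% at 20 to 50 CPM and 0.0265% at 200 CPM or more.

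Lmna, the gene named in the title (ENSMUSG00000028063, mm10 chromosome 3, 88480147 to 88509956, minus strand, protein coding), was close to undetected in both groups. It had 1, 84 and 3 reads in control replicates 1 to 3 and 3, 1 and 41 reads in treated replicates 1 to 3, or 0.038, 3.63, 0.117, 0.119, 0.036 and 1.77 CPM. It did not reach the minimum count for testing, and these counts do not resolve a difference between the groups. With no filter on low counts, edgeR gave a log2 fold change of -0.95 with an SE of 5.04 (edgeR adjusted p = 0.999). Each group had 1 library with nearly all of its Lmna reads, and the libraries read only the 3′ ends of mRNAs, so these counts do not check the treatment labels.

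Between tamoxifen and vehicle, edgeR's quasi-likelihood test found 0 of 7901 genes changed at a Benjamini-Hochberg adjusted p under 0.05 (0 higher, 0 lower; lowest edgeR adjusted p = 0.9996). An unadjusted p under 0.05 was reached by 179 genes, where chance alone would give 395.05. The CPM of the groups did not overlap for 761 genes (9.63%), against 10% by chance. DESeq2 called 149 genes (66 higher and 83 lower with tamoxifen), limma-voom called 7, and edgeR without the filter on low counts called 16. Of the 149 DESeq2 genes, 146 had a mean under 20 CPM and 0 had a mean of at least 100 CPM. The median SE of the log2 fold change was 0.33 over the 1246 genes with a mean of at least 100 CPM. The values that follow are mean ± SD in CPM, control first (n = 3 per group), and log2 fold changes are treated over control with the edgeR SE. No gene named from here on passed the edgeR test over all genes.

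Of 24 sarcomere and 17 calcium handling genes tested, 0 passed edgeR over all genes or adjusted over the list alone. Myl3 (ENSMUSG00000059741, chromosome 9, 110741861 to 110769798) measured 138319 ± 34349 CPM with vehicle and 94985 ± 14927 CPM with tamoxifen, a log2 fold change of -0.54 (SE 0.25). The groups did not overlap for Myl3, but the fold change was -0.34 without control replicate 2, and limma-voom called the gene (limma adjusted p = 5.36e-07). Limma-voom also called Tnnc1, cardiac troponin C, chosen after its values were seen, with a log2 fold change of -0.41 (limma adjusted p = 0.0369). Tpm1, a tropomyosin, measured 34108 ± 3968 and 33360 ± 8152 CPM (log2 fold change -0.03, SE 0.24). The summed sarcomere list measured 279927 ± 46307 and 231131 ± 10301 CPM, a log2 ratio of -0.26 (95% limma interval -0.64 to 0.12). Among calcium handling genes, Pln, the phospholamban that restrains the calcium pump, measured 5454 ± 573 and 4737 ± 1014 CPM, and Atp2a2, the pump itself, 2090 ± 133 and 1772 ± 678 CPM. The calcium handling sum had a log2 ratio of -0.19 (95% limma interval -0.53 to 0.16). Ion channel genes gave -0.19 (-0.52 to 0.15), with Kcnk3, a potassium channel, at 245.6 ± 78.0 and 122.2 ± 67.3 CPM.

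Fetal and hypertrophic stress genes spread widely between libraries. Ankrd1, a stretch-responsive titin-binding repeat protein (ENSMUSG00000024803, chromosome 19, 36111961 to 36120099), measured 19128, 14181 and 6267 CPM in control replicates 1 to 3 and 22178, 59316 and 9924 CPM in treated replicates 1 to 3 (log2 fold change 1.21, SE 0.55). Acta1, the skeletal muscle alpha-actin, measured 1050 ± 477 and 1382 ± 1004 CPM (0.40, SE 0.59; -0.02 without treated replicate 1). Nppa, the atrial natriuretic peptide gene (ENSMUSG00000041616, chromosome 4, 148000722 to 148002079), measured 175 ± 80.2 and 545 ± 521 CPM (1.64, SE 0.63). Of the 16 tested stress genes, 13 had a fold change above 0, and none passed over all genes or adjusted over the list alone. Ankrd1 made up 78.5 to 92.6% of the list's sum in each library. That sum had a log2 ratio of 0.91 (95% limma interval -0.65 to 2.47), and the camera test gave limma adjusted p = 0.775, or adjusted p = 0.980 with an estimated correlation. The direction of the list mean depended on single libraries: the mean difference turned from 0.60 to -0.12 without treated replicate 2 and to -0.25 without control replicate 3. These fits were filtered anew and held 8910 and 8929 genes, against 7901, so the members averaged may differ. Without treated replicate 2 the Ankrd1 log2 fold change was 0.29 and that of Nppa was 0.54. Without control replicate 3 they were 0.87 and 1.90, so both genes kept their direction while the list mean did not. Ankrd1 and Nppa were called by edgeR when no filter on low counts was used (edgeR adjusted p = 1.02e-11 and 8.28e-04). The groups overlapped for both genes. With that setting, 8 of the 10 ways to split the 6 libraries into groups of 3, the real one included, called as many genes.

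**Figure D2:**
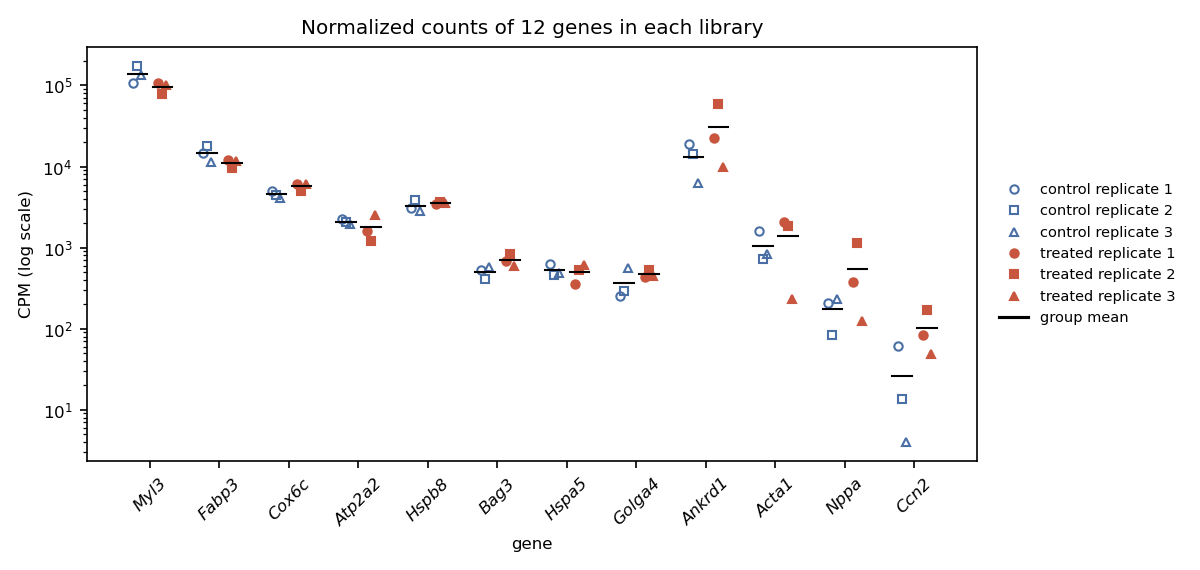
CPM (log axis) of 12 genes in each of the 6 libraries, with vehicle as open blue and tamoxifen as filled red symbols, the symbol shape giving the replicate and a black line the group mean (n = 3). Ankrd1 and Nppa in treated replicate 2, at 59316 and 1128 CPM, lie above the other 5 libraries, while Myl3 spans 77960 to 174624 CPM.

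Energy metabolism genes held 0 that passed edgeR over all genes or adjusted over the list alone. The sum over the 41 tested genes of nuclear-encoded oxidative phosphorylation had a log2 ratio of 0.08 (95% limma interval -0.23 to 0.40). Of these respiratory chain genes, Cox6a2 measured 5929 ± 766 and 5206 ± 124 CPM, and Cox6c 4526 ± 450 and 5713 ± 688 CPM. Fatty acid oxidation genes had a log2 ratio of -0.26 (-0.68 to 0.15), with Fabp3, the heart fatty acid binding protein, at 14643 ± 3135 and 11181 ± 1375 CPM. The tricarboxylic acid cycle gave -0.10 (-0.49 to 0.29), with Mdh2, a malate dehydrogenase, at 2160 ± 207 and 1597 ± 380 CPM without overlap between the groups, and glycolysis 0.04 (-0.27 to 0.35), with Aldoa at 1813 ± 201 and 1661 ± 92.3 CPM. Mitochondrial dynamics and quality control gave -0.06 (-0.36 to 0.23) and the hypoxia response 0.17 (-0.19 to 0.54). Chosen after their values were seen, Cox17, a copper chaperone of cytochrome oxidase, was called by limma-voom (log2 fold change 1.02, limma adjusted p = 0.0403), and Hadh, a fatty acid oxidation enzyme, had an edgeR log2 fold change of -1.22 (SE 0.36) without overlap between the groups.

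The stress responses of the title were measured through lists of their target genes, and none of their members passed the edgeR test over all genes or adjusted over the list alone. Endoplasmic reticulum chaperones had a summed log2 ratio of -0.02 (95% limma interval -0.40 to 0.37), and Hspa5, the main chaperone of that compartment, measured 524.8 ± 87.5 and 501.4 ± 132 CPM. Targets of ATF4, the transcription factor of the integrated stress response, gave -0.09 (-0.41 to 0.23), with Atf5 at 153.1 ± 31.6 and 150.7 ± 37.8 CPM. Golgi structure genes gave 0.10 (-0.26 to 0.47), with Golga4, a golgin, at 367.9 ± 169 and 467.0 ± 53.7 CPM. For Golgi structure the median fold change was -0.12 and the mean difference -0.44, opposite in sign to the sum. The Golgi stress list gave -0.03 (-0.65 to 0.60), a sum made mostly of the heat shock gene Hspb1 at 941.7 ± 190 and 1030 ± 458 CPM, while 10 of its 15 members were below 0 (median -0.44, mean difference -0.62). For the COPI and COPII vesicle coats the log2 ratio was 0.01 (-0.34 to 0.35). Targets of p53 gave 0.17 (-0.35 to 0.69), with Cdkn1a, a cell cycle inhibitor, at 82.9 ± 16.1 and 86.7 ± 79.0 CPM. Heat shock genes gave 0.11 (-0.21 to 0.43), with Hspb8 at 3239 ± 523 and 3561 ± 97.8 CPM. The NRF2 list gave 0.14 (-0.37 to 0.66), autophagy and lysosome genes 0.06 (-0.26 to 0.37), and FOXO targets 0.01 (-0.42 to 0.44). Bag3, a co-chaperone of autophagy, measured 504.2 ± 82.9 and 707.1 ± 126 CPM (log2 fold change 0.49, SE 0.24) without overlap between the groups.

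Genes of the Mediator complex, which links transcription factors to RNA polymerase II, summed to 448.7 ± 38.4 CPM with vehicle and 545.5 ± 68.7 CPM with tamoxifen (log2 ratio 0.28, 95% limma interval -0.08 to 0.64). Med25 (ENSMUSG00000002968, chromosome 7, 44876765 to 44892712), chosen after its values were seen, had 0, 1 and 0 reads in control replicates 1 to 3 and 572, 91 and 18 reads in treated replicates 1 to 3. DESeq2 called it (DESeq2 adjusted p = 0.0217) and edgeR did not (edgeR adjusted p = 0.9996). Its mean over the 6 libraries was 4.45 CPM, below the range in which 40.2% of gene-library pairs held 3 reads or fewer. Med25 was not alone in this. Med6, also chosen after its values were seen, had 0, 0 and 0 reads with vehicle and 219, 568 and 265 with tamoxifen. DESeq2 called Med6 as well (DESeq2 adjusted p = 3.10e-04), at a mean of 6.75 CPM. The pattern was not particular to Mediator: in 125 of the 149 DESeq2 calls a whole group had 3 reads or fewer. Ets1 of the Golgi stress list had 221, 309 and 630 reads with vehicle and 0, 0 and 2 with tamoxifen. Gadd45b of the p53 list had 0, 0 and 0 and 410, 227 and 16. Both were chosen after their values were seen. Of the 24 tested Mediator genes, 14 had a fold change above 0 and 10 below. The most abundant members, Med28 and Med4, measured 109.7 ± 21.7 and 96.2 ± 34.3 CPM, and 32.7 ± 20.7 and 74.8 ± 40.2 CPM. For extracellular matrix genes the log2 ratio was 0.21 (-0.48 to 0.89), and for secreted profibrotic factors 0.61 (-0.10 to 1.33). Weighted equally, the 25 tested extracellular matrix genes had a mean difference of 1.42 and a median fold change of 0.65, with 18 above 0 and 7 below. Ccn2, a matricellular growth factor, measured 26.0 ± 30.3 and 101.6 ± 63.5 CPM (log2 fold change 1.97, SE 0.86; 1.36 without treated replicate 2 and 3.54 without control replicate 1). Camera reached an unadjusted p under 0.05 for 2 lists, Mediator and extracellular matrix, both with limma adjusted p = 0.459, and adjusted p = 0.980 with an estimated correlation. The lists of this and the preceding paragraph were drawn up with knowledge of the published study's themes, so they are not independent evidence.

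Type I interferon genes summed to 125 ± 27.4 and 95.3 ± 9.11 CPM (log2 ratio -0.37, 95% limma interval -0.84 to 0.10), and antigen presentation genes gave -0.08 (-0.68 to 0.52). Inflammatory genes gave 0.24 (-0.20 to 0.67), most of it Sod2, a mitochondrial superoxide dismutase, at 1123 ± 188 and 1332 ± 199 CPM. Immediate early genes gave 0.23 (-0.53 to 0.99), cell death genes 0.00 (-0.31 to 0.31), and cell cycle genes -0.17 (-0.59 to 0.26). In the cell cycle list, Cenpa, a centromeric histone, measured 108.9 ± 30.3 and 50.7 ± 5.12 CPM without overlap between the groups. Among structural lists, the intercalated disc gave 0.22 (-0.18 to 0.63), microtubules and intermediate filaments 0.06 (-0.28 to 0.40), and the nuclear envelope 0.03 (-0.36 to 0.43), where Emd, the gene for emerin, measured 127.2 ± 37.8 and 82.5 ± 10.5 CPM. Ribosomal proteins gave 0.06 (-0.31 to 0.43), the proteasome 0.05 (-0.27 to 0.36), and cholesterol synthesis 0.22 (-0.46 to 0.90). The circadian clock gave -0.01 (-0.79 to 0.77), and estrogen receptor targets, which tamoxifen itself can affect, 0.02 (-0.71 to 0.75). That sum follows the abundant members. Weighted equally, the 7 tested estrogen receptor targets had a mean difference of 1.60 and a median fold change of 0.05 (camera, limma adjusted p = 0.792). A direct effect of tamoxifen on these targets is therefore not settled by the sum.

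Summed markers of other heart cells overlapped between the groups in every list. Fibroblast markers summed to 162 ± 53.6 CPM with vehicle and 183 ± 11.4 CPM with tamoxifen (log2 ratio 0.24, 95% limma interval -0.35 to 0.82). Endothelial markers gave 0.41 (-0.49 to 1.31) and macrophage markers 0.23 (-0.77 to 1.22), with Fabp4, an endothelial fatty acid binding protein, at 68.5 ± 15.6 and 112.0 ± 48.3 CPM. Smooth muscle and pericyte markers gave 0.10 (-0.26 to 0.47), a sum made mostly of Des, the desmin gene that cardiomyocytes also use. Atrial markers gave 0.94 (-0.37 to 2.26), a sum made mostly of Nppa. Another 8 lists had fewer than 5 tested members and were not tested. Their sums were 2.65 ± 4.59 and 7.45 ± 11.9 CPM for lymphocytes and granulocytes, 114 ± 57.3 and 136 ± 103 CPM for the epicardium, and 100.1 ± 22.2 and 112 ± 47.7 CPM for Schwann cells and neurons. Adipocyte markers summed to 292 ± 30.6 and 230.3 ± 44.3 CPM, erythroid markers to 1456 ± 382 and 1774 ± 901 CPM, sex-linked genes to 74.8 ± 67.2 and 130.3 ± 124 CPM, and nuclear-retained long noncoding RNAs to 871 ± 372 and 918 ± 219 CPM. The table held 0 genes of the mitochondrial genome.

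Over the 42 tested lists, camera called 0 at a limma adjusted p under 0.05, with the preset correlation (lowest adjusted p = 0.459) and with an estimated one (lowest adjusted p = 0.980). Fry called 0 for a shift in one direction and 5 for changes in either direction: Mediator, Golgi stress, cell cycle, vesicle coats, and immediate early genes. In 37 of the 42 lists the 95% limma interval of the summed ratio lay within 1 of 0 on the log2 scale, and it reached further in the other 5: stress genes, profibrotic factors, endothelial, macrophage and atrial markers. These intervals are per list and were not widened for the number of lists. They describe mainly the abundant members. Among the 37 lists, the mean difference, which weights members equally, exceeded 1 for estrogen receptor targets (1.60), extracellular matrix (1.42), Mediator (1.08) and fibroblast markers (1.07). In 16 lists the median fold change, the mean difference and the camera direction did not share a sign: sarcomere, calcium handling, ion channels, microtubules, nuclear envelope, ATF4 targets, endoplasmic reticulum chaperones, vesicle coats, interferon, antigen presentation, immediate early, FOXO, autophagy, cell cycle, circadian clock and atrial markers. The summed ratio and the mean difference had opposite signs in 12 lists. In simulated counts with known changes drawn from genes of at least 100 CPM, edgeR recovered 8% of 2-fold, 66% of 4-fold, 88% of 8-fold and 96% of 16-fold changes. For changes drawn from all tested genes it recovered 0, 20, 24 and 40%. Simulated genes followed a dispersion trend over abundance, with no gene-specific part. On the real counts only 179 genes had an unadjusted edgeR p under 0.05, where chance alone would give 395.05. These recovery rates may therefore be too high for the real comparison.

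**Figure D3:**
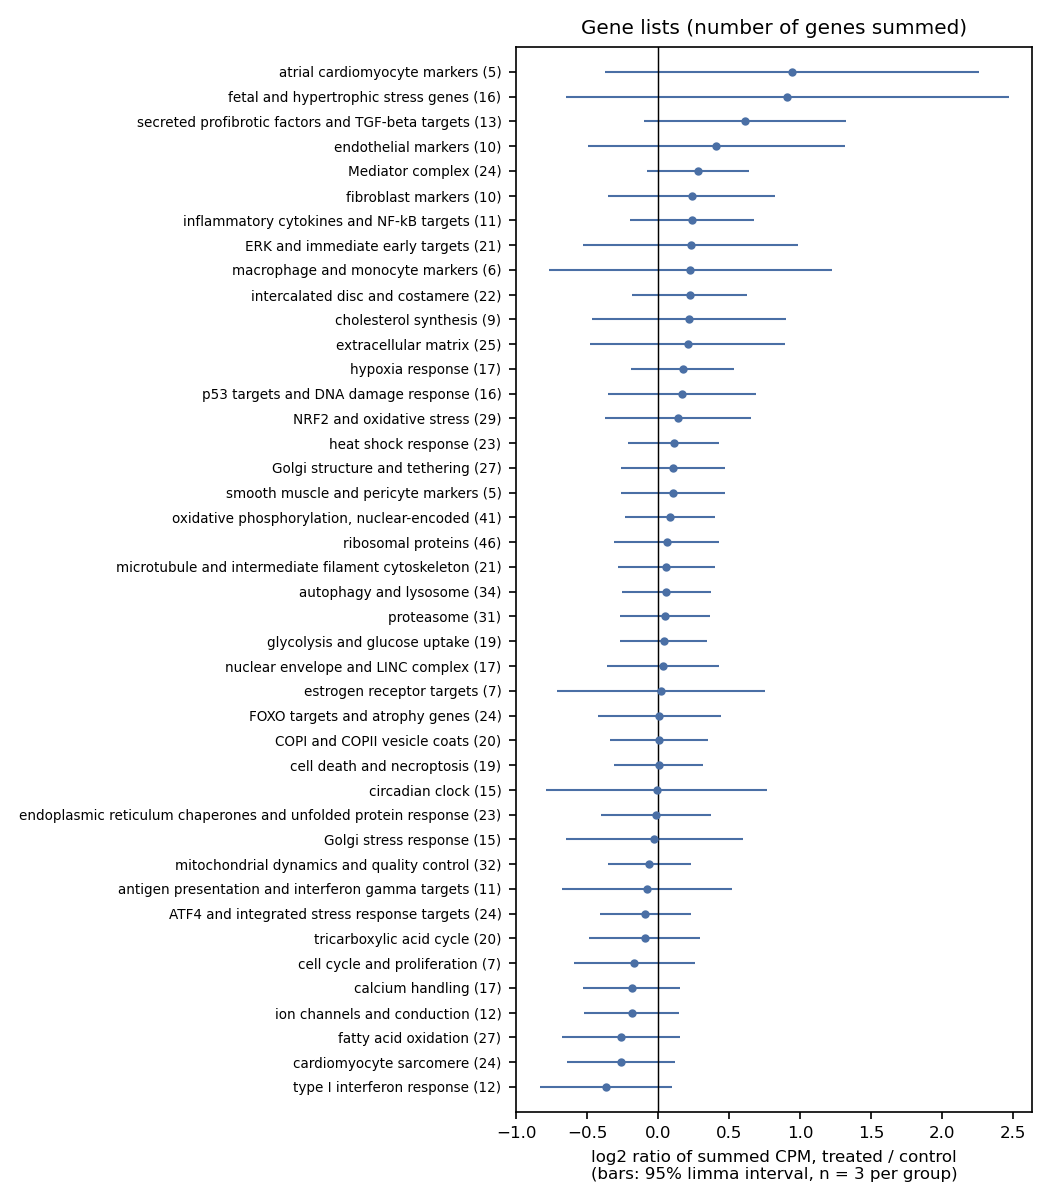
Log2 ratio of summed CPM, treated over control, for the 42 tested lists (points), with 95% limma intervals (bars, n = 3 per group) and the number of genes summed in parentheses. All 42 intervals include 0; the stress gene interval is the widest, from -0.65 to 2.47.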

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

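Tests on genes of at least 100 CPM, on pseudogene sums, on list sums and with fry in either direction were chosen after seeing the data. The count of changed genes, 0 with edgeR, stayed 0 with RLE factors, upper-quartile factors, a minimum count of 50, robust dispersion, genes of at least 100 CPM (edgeR and DESeq2) and pseudogene sums. It was 149 with DESeq2 (66 higher, 83 lower), 7 with limma-voom (3 higher, 4 lower) and 16 without a filter on low counts (10 higher, 6 lower); for limma-voom and the filter the cause was not tested. Leaving out 1 library at a time gave 0 to 1 genes (0 to 1 higher, 0 to 0 lower). The 1 call came without control replicate 1: Akap2, named after its values were seen, with 0 and 0 reads in the other controls and 1679, 6014 and 1029 with tamoxifen, against 2078 in the library left out. The count of changed lists was 0 under every camera setting and with fry in one direction, and 5 with fry in either direction; the cause was not tested. Without treated replicate 3 the stress list came closest (limma adjusted p = 0.0644), and over the alternatives its adjusted p reached 0.995, without treated replicate 2; its mean difference turned negative there and without control replicate 3. Correlations of deviations did not show that replicate numbers pair the samples (0.0050, -0.0035 and -0.021 for same-numbered libraries), though replicate 3 of both groups shares low Ddx3y reads; with the replicate number as a block edgeR called 0 genes and camera 0 lists. For 89 genes, those named by rule and others chosen after their values were seen, and for the 42 lists, 1377 of 1462 and 536 of 588 alternative values kept their direction and their side of the threshold; 13 gene values passed it and the remainder changed sign without a call. The 13 values belong to Myl3, Ankrd1 and Nppa, named by rule, and to Med25, Ubxn4, Ndufs5, BC002163, Cox17 and Rpl23a-ps3, which were not. All 13 came from limma-voom, DESeq2 or edgeR without the filter, and none from leaving out a library. Without treated replicate 2 every gene in the edgeR fit had an adjusted p of at least 0.9999, so that value does not single out these 9 genes. Lmna falls below the filter, so it has no main fold change to compare; DESeq2 gave -1.02 with an SE of 3.47 and no adjusted p. Genes under about 20 CPM often held 3 reads or fewer in single libraries (18.6% of gene-library pairs at 10 to 20 CPM). The number of reads sequenced is argued against as the only limit. Per library, 274 to 470 genes had at least 10 reads there and fewer than 10 in every other library. Their median was 110 to 241.5 reads in that library, although library totals were similar (23057044 to 27545424 counts). What else limits these genes was not tested.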

Other observations

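The tests of low abundance, of other cell types, of atrial tissue, of a response to treatment in the stress list and of shared reads were chosen only after the results were seen; the counts over other splits were planned. Genes named in this part were chosen after their values were seen.

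Treated replicate 2 had the most genes that were high in 1 library alone. Of 2116 genes with a mean of at least 50 CPM, 25 were more than 2-fold above all other libraries in it, against 8, 12 and 9 in control replicates 1 to 3 and 7 and 3 in treated replicates 1 and 3. It stood less apart in genes below 0.5 times all other libraries, 64 against 20, 58 and 60 in control replicates 1 to 3 and 42 and 22 in treated replicates 1 and 3. Hbegf, an epidermal growth factor receptor ligand, measured 152 CPM against at most 47.9 elsewhere, and Ankrd23, a relative of Ankrd1, 1975 against 844. Atf3, a stress-induced transcription factor, had 3223 reads there and 3 to 195 in the other 5 libraries. Y-linked Ddx3y had 3425 and 2165 reads in control replicates 1 and 2 and 6241 and 4005 in treated replicates 1 and 2, but 5 and 8 in replicate 3 of each group. Xist, expressed from the inactive X chromosome, had 217 and 11 reads in those 2 libraries and 0 in the other 4. Other Y-linked genes had few reads, and not in every library with Ddx3y reads. Eif2s3y had 343 and 322 in treated replicates 1 and 2 and at most 3 elsewhere. Uty had 260 in control replicate 1 and at most 1 elsewhere. Both had 0 in replicate 3 of each group, while Kdm5d had at most 3 reads, in treated replicate 3. Among genes of at least 50 CPM without overlap between groups, Ubxn4, linked to degradation at the endoplasmic reticulum, measured 29.7, 22.3 and 24.0 CPM with vehicle and 120.6, 109.2 and 62.2 CPM with tamoxifen (log2 fold change 1.94, SE 0.51), and Hadh, a fatty acid oxidation enzyme, 274, 491 and 325 CPM and 110.4, 118 and 239 CPM (-1.22, SE 0.36). Neither passed edgeR (adjusted p = 0.9996); DESeq2 called Ubxn4 (DESeq2 adjusted p = 0.0346) but not Hadh (0.0869).

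DESeq2 called 149 genes where edgeR called 0. A treatment effect as the source of that count as a whole is argued against by the other 9 splits of the 6 libraries into groups of 3, which gave a median of 179 DESeq2 calls (134 to 233); this excludes no single gene. A candidate explanation is that few molecules per gene were captured: 98.0% of the calls had a mean under 20 CPM, against 51.4% of the 7997 genes with an adjusted p. In 125 of the calls a whole group had 3 reads or fewer, as in Sacm1l, with 0, 0 and 0 reads with vehicle and 585, 972 and 135 with tamoxifen. On simulated counts, which had no step for lost molecules, DESeq2 made 105 and 147 false calls. Low means among the real calls therefore do not separate few captured molecules from false calls that DESeq2 makes at this spread. Which called genes differ between the treatments stays open.

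The stress list was high in treated replicate 2, at 64058 summed CPM against 7982 to 25755 in the other 5 libraries, a log2 ratio of 1.96 to their mean; Ankrd1 made up 92.6% of that sum, and without it the ratio was 1.15. Other cell types stay open: 9 marker lists had a median log2 ratio of 0.20 (SD 1.09), but epicardial (1.34, from Clu alone), erythroid (0.99) and macrophage (0.90) markers came near the value without Ankrd1. Atrial tissue stays open: Myl7, Sln, Bmp10 and Myl4 had 0 reads there, but Myl7, Sln and Bmp10 had 0 in all 6 libraries, and Myl4, with 130 and 24 reads in control replicates 1 and 2 and at most 1 elsewhere, is too low to decide. A response to tamoxifen cannot be told apart from variation between libraries: 2 treated libraries lay above the highest control, while the third lay among the controls, or below all 3 of them without Ankrd1.

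Ndufs5, a complex I subunit (chromosome 4, 123712710 to 123718202), and BC002163, a processed pseudogene (chromosome 16, 42955631 to 42955949), went opposite ways, with edgeR log2 fold changes of 1.52 (SE 0.76) and -1.26 (SE 0.56), both called by limma-voom (limma adjusted p = 0.00177 and 0.0296). Reads shared between the copies are a candidate explanation, as 81.0% of the 289 words of 31 bases in BC002163 also occur in Ndufs5 transcripts and the summed counts changed by only 0.12 (SE 0.21). The 2 genes also went opposite ways within the vehicle group alone. In control replicates 1 to 3 Ndufs5 measured 550, 191 and 19.2 CPM and BC002163 418, 717 and 901 CPM. Their sum there was 932 ± 31.4 CPM. The sum bears on Ndufs5 alone only if the copies share reads, and these values without tamoxifen go with sharing. Given sharing, 2 SE above the change of the sum is 0.54, below the Ndufs5 values of 1.52 with edgeR and 2.50 with limma-voom. This does not decide against a rise in Ndufs5 mRNA. BC002163 itself lay more than 2 SE below 0, and a true fall in it could offset a rise in the sum. A change in Ndufs5 mRNA therefore stays open.

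With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split and the highest other split gave 0 and 1 genes with edgeR, 149 and 233 with DESeq2, 7 and 15 with limma-voom, and 16 and 25 with edgeR without the filter on low counts. For lists they gave 0 and 2 with camera, and 5 and 9 with fry in either direction. In that order, 10, 9, 3, 8, 10 and 7 of the 10 splits, the real one included, gave as many calls.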
